A study of Homo sapiens with 16 samples.

How the data were processed

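Gene expression was measured by spatial transcriptomics in frozen sections of human cutaneous squamous cell carcinoma, a cancer of epidermal keratinocytes. In this assay a section is laid on a glass array whose spots carry barcoded poly-T primers, so that each captured RNA keeps the position of its spot. A spot covers a small area that can hold several cells of different types. The 16 sections came from 6 tumours, called here tumours A to F. Tumours A to D had 3 sections each on the earlier Spatial Transcriptomics array (ST, square grid), and tumours E and F had 2 sections each on the Visium array (hexagonal grid). Sections of a tumour are technical replicates, so the tumour was the unit of replication wherever regions were compared.

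The deposited tables hold counts of unique molecular identifiers (UMIs) per spot and gene, with no normalization by the authors, as far as the values show. The genome build was GRCh38, and Visium reads were processed with Space Ranger 1.0.0 and trimmed with cutadapt, per the submitters' processing notes; the version of cutadapt is not given in the sources used here. The aligner and counter of the ST sections are not given in the sources used here. The deposited tissue selections list the array coordinates of the ST spots that the authors placed over tissue, and the deposited Visium matrices and position tables do the same for Visium. Combined tables of the series, which hold a subset of the spots and genes, and a table of barcode coordinates were not used, because no region annotation was found in them. Coordinates of named genes come from the RefSeq annotation of GRCh38.

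Only spots over tissue were used. They numbered 17599, of which 12769 had at least 500 UMIs and were kept, 6448 on ST and 6321 on Visium. The kept share was 99.7% in tumour A, 93.4% in B, 48.0% in C, 79.7% in D, 94.0% in E and 66.3% in F. The ST tables list 25348 genes and Visium 33418, and comparisons that pool platforms used the 19550 shared names. Shared names lacked 3 genes of the T cell list, 6 immunoglobulin genes of the B and plasma cell list, SOX10 of the Schwann cell list, and the newer symbols of CTGF and CYR61.

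Spots were classed by the log2 ratio of the UMIs of 12 keratinocyte genes to those of 12 stromal genes, with 0.5 added to each. In each section the spots were ranked by the ratio and split into 3 equal groups; the highest was called keratinocyte-rich, the lowest stroma-rich, and the middle group was left out. These classes are ranges of a continuous ratio and not cell types. Among keratinocyte-rich spots, an edge spot had at least 1 stroma-rich spot among its direct neighbours (8 on ST, 6 on Visium), and an interior spot had none and at least 3 neighbours over tissue. Each section had to hold at least 5 spots of both kinds. The grids differ in pitch, so the edge reaches a different distance on each platform. The 24 ratio genes were left out of tests and lists.

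UMI counts were summed per tumour and class, giving 12 sums per contrast, and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM normalization, filterByExpr) with the tumour as a block. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera of limma 3.58.1 on voom values of the same sums, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. camera sets a list against the other genes, while fry asks whether the genes of a list move one way on balance. Across spots, list UMIs per 10000 were related by partial Spearman correlation adjusted for the spot total, per section, averaged per tumour, and tested over the 6 tumours by an exact two-sided sign-flip permutation test whose smallest p is 0.03125. Differences between tumours were tested with edgeR on UMI counts summed per section, within each platform. Those p-values measure the spread between sections of a tumour only. The platform by region interaction was tested on the 12 sums, and platform and patient cannot be told apart.

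The 28 lists cover tumour-specific keratinocyte, basal keratinocyte, differentiated keratinocyte, cell cycle, invasion and matrix remodelling, fibroblast, pericyte and smooth muscle, endothelial, lymphatic endothelial, macrophage and myeloid, dendritic and Langerhans, neutrophil, mast cell, T cell, regulatory T and checkpoint, B and plasma cell, melanocyte, sweat and sebaceous gland, skeletal muscle, adipocyte, Schwann cell, red blood cell, interferon response, interferon gamma and antigen presentation, hypoxia and glycolysis, stress and immediate early, mitochondrial, and TGF-beta ligand and target genes. The groups, tests, lists, class definitions and the rule for named genes were fixed before the data were examined. Named genes of each contrast were the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes with adjusted p under 0.05, average log2 CPM of at least 5 and the same sign in every tumour. The 10 tumour-specific keratinocyte genes and FOXP3, CTLA4, CD274, PDCD1 and CD8A were named in advance, with up to 4 members per list. Per tumour, the 4 genes with the largest log2 fold change against the other tumours of its platform were named, if higher in each of its sections than in every other section. A few genes that met these rules are left out of the text. A gene whose level could point to a detail that the records leave out was not named, and neither were sex-linked markers of a person.

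Totals over tissue ranged from 998796 to 14749204 UMIs per section, and the median per spot from 289 to 16683. The steps were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. For stroma-rich against keratinocyte-rich sums (12738 genes), 8.93% of genes changed by 0.5 on the log2 scale, 72.9% of those changed by 1 and 98.1% of those changed by 2 were recovered, and 3.25% of calls were false. For edge against interior sums (11285 genes) the shares recovered were 57.9%, 90.4% and 100%, with 7.82% false. For the ST tumours (11748 genes) they were 28.6%, 73.0% and 92.2%, with 5.38% false, and for the Visium tumours (14165 genes) 4.84%, 54.5% and 87.7%, with 1.03% false. Both changed lists were found in each contrast with 0 others called. The simulated genes varied independently of each other, so this does not test the list methods where genes of a list vary together. A simulated partial correlation of 0.3 was recovered as 0.297 on average, and one of 0 as 0.00987.

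Alternatives tried were DESeq2 1.42.0 (size factors and its own test), no expression filter beyond 10 counts, splits into 4 or 2 groups in place of 3, another pair of ratio lists, all spots or spots of at least 1000 UMIs, each spot thinned to 500 UMIs, each platform alone, each tumour or section left out, no tumour block, sums per section with and without the section number as a block, interior spots matched to edge spots on the ratio within 0.25 log2 units, the stromal share as a covariate in voom, voom without it, and a stricter edge definition. Correlations were also computed with neighbouring spots, with other adjustments and in keratinocyte-rich spots alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 handled the spots and drew the plots.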

Results

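RNA was counted at array spots over 16 sections of 6 cutaneous squamous cell carcinomas, 12 sections of 4 tumours (A to D) on the ST array and 4 sections of 2 tumours (E and F) on Visium. The median UMI count per spot lay between 5382 and 7216 in the sections of tumour A, 1648 and 2844 in B, 289 and 602 in C, 675 and 1816 in D, 15711 and 16683 in E, and 635 and 982 in F. Tumours C and F were thus the shallowest, with 48.0% and 66.3% of their tissue spots passing the minimum of 500 UMIs. In sections 1, 2 and 3 of tumour C the median was 602, 567 and 289 over tissue and 418, 323 and 271.5 outside it. Its tissue spots thus stood little above the positions outside the tissue, least in section 3. Every pair of sections of a tumour differed by more than sampling noise, with a chi-square per degree of freedom of 2.08 to 46.9 over genes, so all sections were kept. Sections 2 and 3 of tumour B carried the same 521 selected array positions, although their counts differed (2.78 per degree of freedom). Whether 1 selection was reused for both is not known, so it is uncertain which spots of these sections lay over tissue. The study asked how tumour cell states and the surrounding stroma and immune cells are arranged, and what marks the tumour edge that faces the stroma.

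The classes comprised 4262 keratinocyte-rich and 4263 stroma-rich spots. In the median section, the 12 stromal genes took 73.4 of 10000 UMIs in stroma-rich spots and 16.5 in keratinocyte-rich spots, while the 12 keratinocyte genes took 662.5 and 1079. Stroma-rich spots therefore still held much keratinocyte RNA, and 42.9% of all spots lay within 0.5 log2 units of a class boundary. The mean log2 ratio of stroma-rich spots ran from -0.28 to 3.83 over sections, with a median of 2.98. The classes also differed in depth. The median UMI count per spot had a median over sections of 3207 in keratinocyte-rich and 1898 in stroma-rich spots. Within a section the pair ranged from 32520 against 6729 (tumour E, section 2) to 1994 against 2073 (tumour B, section 3).

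Stroma-rich spots carried more RNA of plasma and B cells, fibroblasts, vessels and myeloid cells than keratinocyte-rich spots, and less RNA of the cornifying epidermis. JCHAIN, which joins secreted antibodies into polymers, averaged 399.9 ± 268 CPM in stroma-rich and 81.7 ± 153 CPM in keratinocyte-rich sums (SD, n = 6 tumours). CXCL12, a chemokine that attracts leukocytes, averaged 137 ± 193 against 9.36 ± 8.19 CPM, with a fitted log2 fold change of 3.49 (SE 0.38, edgeR adjusted p = 4.57e-04). SPRR1A, a structural protein of the cornified envelope, showed the opposite pattern, with 26.9 ± 23.7 CPM in stroma-rich and 209 ± 230 CPM in keratinocyte-rich sums (log2 fold change -2.91, SE 0.30, edgeR adjusted p = 4.18e-04). Each of these 3 genes kept its direction in 6 of 6 tumours, which the rule for naming genes required. In tumour C JCHAIN was only 0.035 higher on the log2 scale. CXCL12 lies on chromosome 10 (44370165 to 44385097, GRCh38), SPRR1A on chromosome 1 (152984081 to 152985814) and JCHAIN on chromosome 4 (70655541 to 70666508).

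Of 12965 genes tested with edgeR, 2114 were higher in stroma-rich and 2097 higher in keratinocyte-rich spots at an adjusted p under 0.05, and 3020 of these 4211 had the same direction in all 6 tumours. Among called genes with an average log2 CPM of at least 5 and the same direction in every tumour, the 12 largest rises ranged from 2.96 to 3.54 on the log2 scale. They included the B cell receptor component CD79A (3.54, SE 0.56), the lymphoid chemokine CCL19 (3.50, SE 0.48), the plasma cell gene DERL3 (3.37, SE 0.46), complement C3 (3.36, SE 0.60) and the extracellular superoxide dismutase SOD3 (3.08, SE 0.35). Matrix genes among them were the serine protease HTRA3 (3.12), the Wnt modulator SFRP2, the proteoglycan VCAN (2.96) and the procollagen processing enhancer PCOLCE; PTGDS, a prostaglandin synthase, had 3.11. Under the same limits, the 12 largest falls ran down to the -2.91 of SPRR1A. They included the antimicrobial proteins DEFB4A (-2.13) and S100A7A (-1.93), the elastase inhibitor PI3 (-1.86), the phospholipase PLA2G3 (-1.89), the calcium binding protein CALB2 (-1.85), the retinol dehydrogenase RDH12 (-1.84), the airway-type protease TMPRSS11D (-1.82) and the transglutaminase TGM1 (-1.82). FAM25A (-2.44), FAM25G (-2.57), SPRR2F (-1.81), S100A7A and DEFB4A have near-identical copies in the genome, so the division of their reads among copies is uncertain.

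Because the classes were ranked on keratinocyte and stromal genes of the same counts, lists of either tissue tend to follow them by construction. The list of keratinocyte differentiation genes was lower in stroma-rich spots without exception. All 24 measured members fell, 24 also when adjusted over the list alone, among them KRT1 (log2 fold change -1.40), KRT10 (-1.20), KRTDAP (-1.70) and the protease KLK7 (-1.64). camera gave an adjusted p of 4.77e-14 with the preset correlation, and adjusted p = 0.26 with an estimated correlation. Basal genes did not follow: of 15 members, 2 fell, CD44 (-0.49) and EGFR (-0.57), 13 did not pass, 0 were called when adjusted over the list alone, and the camera adjusted p was 0.511. None of 22 cell cycle genes passed in either direction (camera adjusted p = 0.635), nor did any when adjusted over the list alone. Hypoxia and glycolysis genes were lower in stroma-rich spots, 10 of 15 falling (12 when adjusted over the list alone), including BNIP3 (-1.27), HK2 (-1.37), ANGPTL4 (-1.30) and VEGFA (-0.90); camera gave 1.33e-04, and adjusted p = 0.328 with an estimated correlation. Stress and immediate early genes fell in 10 of 14 cases (10 adjusted over the list alone), led by the heat shock genes HSPA1B (-0.94) and HSPB1 (-1.06), with a camera adjusted p of 9.23e-04 and adjusted p = 0.292 with an estimated correlation.

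Vessel and connective tissue genes were higher in stroma-rich spots, which were chosen by stromal genes of the same counts. Their rise, most directly that of fibroblast genes, follows in part from that choice and is no independent support. All 18 endothelial genes rose, such as VWF (2.26), ACKR1 (3.56) and ESAM (2.66), as did all 6 lymphatic endothelial genes, such as LYVE1 (3.05) and CCL21 (2.57), and 19 of 20 fibroblast genes, such as CTHRC1 (2.69), DPT (3.17) and PDGFRB (2.44). Of 11 pericyte and smooth muscle genes 9 rose, including MYL9 and TAGLN (2.47 and 2.46). These counts were the same when adjusted over the list alone. The camera adjusted p was 2.97e-14 for endothelial, 5.19e-05 for lymphatic, 4.77e-14 for fibroblast and 1.44e-05 for pericyte genes, and for each of these 4 lists adjusted p = 0.211 with an estimated correlation. TGF-beta ligands and targets rose in 8 of 13 cases (10 adjusted over the list alone), including CTGF (2.54), CYR61 (1.73) and TGFB3 (1.73), with camera adjusted p = 2.75e-05 and adjusted p = 0.26 with an estimated correlation. Of 26 invasion and matrix remodelling genes, 11 rose and 15 did not pass, also when adjusted over the list alone. Those that rose included the mesenchymal transcription factors ZEB1 (2.22) and TWIST1 (2.28) and the metalloproteinase MMP11 (1.92), and camera gave 0.00141, with adjusted p = 0.414 with an estimated correlation.

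Immune lists were higher in stroma-rich spots as well. Macrophage and myeloid genes rose in 16 of 17 cases, for example CD163 (2.48), MRC1 (2.44) and C1QA (2.13), and the 1 exception was CD68 (0.01, with a per-tumour change other than 0 only in the 2 Visium tumours). T cell genes rose in 14 of 15 cases (15 adjusted over the list alone), for example NKG7 (2.40) and CD2 (1.68), and CD8A was 1.88 higher (SE 0.49, edgeR adjusted p = 0.0147, 6 of 6 tumours). Regulatory T and checkpoint genes rose in 10 of 14 cases, including FOXP3 at 1.44 (SE 0.30, edgeR adjusted p = 0.00455), CTLA4 at 1.76 (SE 0.34, edgeR adjusted p = 0.00291) and PDCD1 at 2.30 (SE 0.51, edgeR adjusted p = 0.00602), each in 6 of 6 tumours. The checkpoint ligand gene CD274 did not pass (-0.18, SE 0.28, edgeR adjusted p = 0.663). B and plasma cell genes rose in 8 of 10 cases (9 adjusted over the list alone), including TNFRSF17 (4.00), while SDC1, which keratinocytes also express, fell (-0.85). Mast cell genes rose in 5 of 6 cases, led by the tryptase gene TPSB2 (2.26). Counts with no second value were the same when adjusted over the list alone.

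camera gave adjusted p-values of 3.22e-08 for macrophage, 1.03e-07 for T cell, 1.05e-05 for regulatory T, 5.19e-05 for B and plasma cell and 2.34e-04 for mast cell genes. In the same order the lists had adjusted p = 0.211, 0.272, 0.211, 0.26 and 0.281 with an estimated correlation. Interferon gamma and antigen presentation genes rose in 8 of 15 cases, including PSMB9 (0.85), CIITA (1.24), CD74 (1.08) and HLA-DRA (1.05), and 9 rose and 1 fell when adjusted over the list alone. Their camera adjusted p was 0.0186, with adjusted p = 0.319 with an estimated correlation. The interferon response list was not called (0 rose, 3 of 15 fell, 2 adjusted over the list alone, camera adjusted p = 0.226); its falling members were IFI27 (-1.05), OAS1 (-0.85) and IFIT1 (-0.54).

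Dendritic cell genes went both ways. CCR7, carried by migrating dendritic cells and lymphocytes, was 2.72 higher in stroma-rich spots, while the Langerhans cell genes CD207 (-1.54) and CD1A (-1.12) were lower; 5 of 10 rose and 2 fell, also when adjusted over the list alone, and the camera adjusted p was 0.145. Neutrophil genes likewise split, 3 of 10 rising, such as CSF3R (1.64), and 2 falling, CXCR2 (-1.55) and S100A12 (-1.39), also when adjusted over the list alone (camera adjusted p = 0.836). Sweat and sebaceous gland genes rose in 6 of 14 cases, including DCD (3.32) and SCGB2A2 (3.31), and fell in 2, MGST1 (-0.83) and SOX9 (-0.72). Adjusted over the list alone, 7 rose and 2 fell. For this list camera gave 0.0309, and adjusted p = 0.289 with an estimated correlation. Its mean was higher in 4 of 6 tumours, with 2.01 in A, 0.41 to 0.80 in B, D and F, -0.51 in C and -0.30 in E. DCD was higher in 4 tumours and lower in 2. Of the 10 mitochondrial transcripts only MT-CO1 passed (-0.51), 0 did when adjusted over the list alone, and camera gave 0.0459, with adjusted p = 0.414 with an estimated correlation.

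Lists of cells that the sections could also hold were not called by camera: melanocyte (1 of 6 higher, MITF at 0.94, adjusted p = 0.962), skeletal muscle (1 of 4, TTN at 1.91, 0.962), Schwann cell (2 of 4, CDH19 at 1.89 and NCAM1 at 1.51, 0.230) and red blood cell genes (2 of 3, HBA2 at 2.46 and HBA1 at 1.46, 0.0812). Of 3 adipocyte genes FABP4 (3.62) and LPL (2.05) rose and CIDEA (-1.27) fell (camera adjusted p = 0.356). Adjusted over the list alone, these counts were the same except for skeletal muscle, with 0. The melanocyte list had a negative mean and median log2 fold change and the neutrophil list a negative median, although camera gave both an upward direction.

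The tumour-specific keratinocyte list showed no common direction between the 2 classes. Of its 10 genes, NT5E (1.30, SE 0.26, edgeR adjusted p = 0.00439), IL24 (1.14, SE 0.35, edgeR adjusted p = 0.0306), KCNMA1 (0.80, SE 0.20, edgeR adjusted p = 0.0123) and INHBA (0.53, SE 0.17, edgeR adjusted p = 0.0341) were higher in stroma-rich spots. INHBA had -0.03 and was not called with each spot thinned to 500 UMIs. PTHLH, the parathyroid hormone-like hormone, was lower (-0.94, SE 0.33, edgeR adjusted p = 0.0481, lower in 5 of 6 tumours). The 5 others did not pass, among them FEZ1 (0.44), MAGEA4 (-0.49), MMP10 (-0.55) and SLITRK6 (-0.57). Adjusted over the list alone, 4 rose and 1 fell; because the study chose this list on cells that include these patients, that count is not independent evidence. The camera adjusted p was 0.635, with adjusted p = 0.914 with an estimated correlation.

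Over the whole contrast camera called 17 of 28 lists with the preset correlation and 0 with an estimated one, and fry called 19. With each spot thinned to 500 UMIs edgeR called 986 genes, with the ST tumours alone 971, and with the Visium tumours alone 2042; without tumour A it called 2382 and without tumour F 2806.

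**Figure D1:**
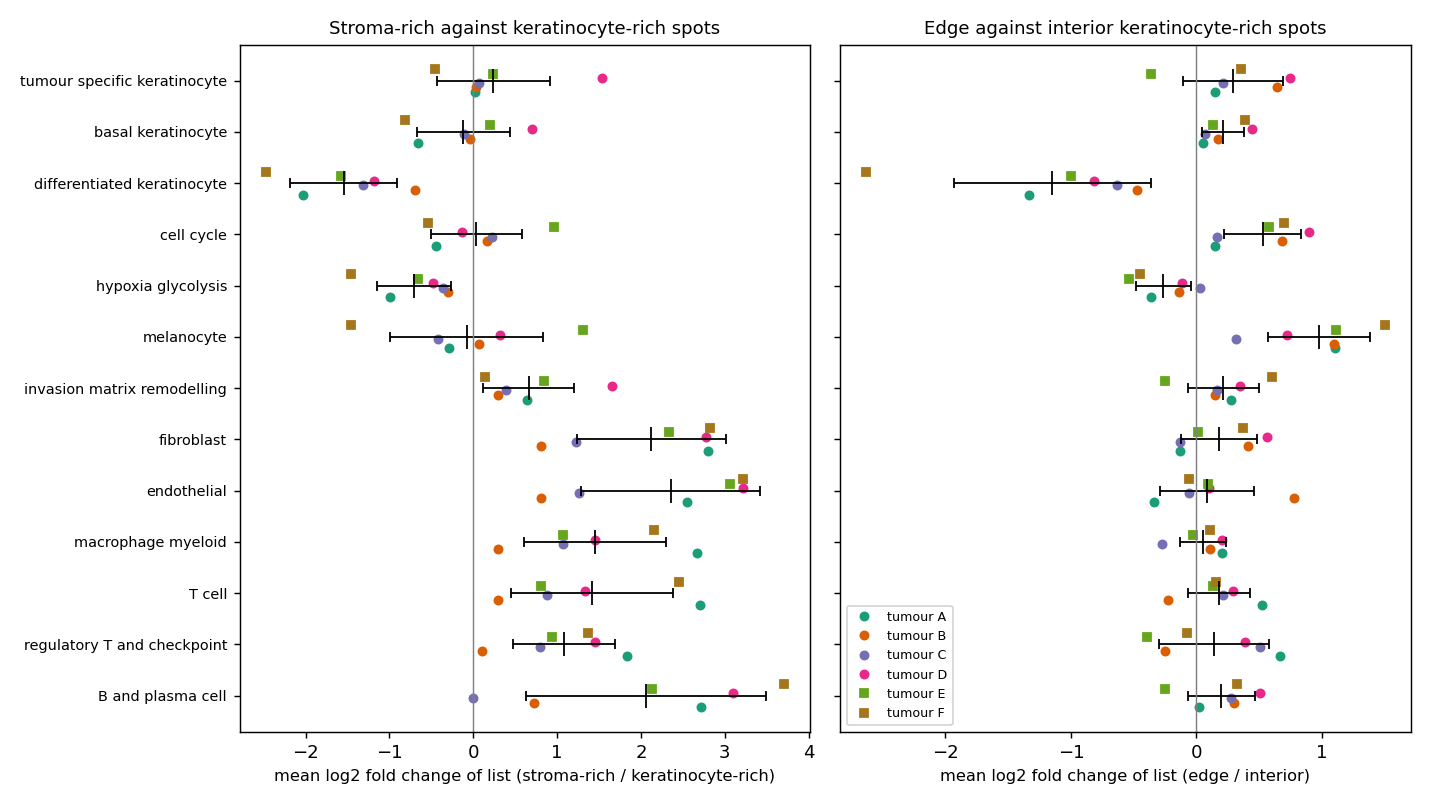
Mean log2 fold change of 13 gene lists in each tumour (circles, ST; squares, Visium), for stroma-rich over keratinocyte-rich spots (left) and edge over interior spots (right); bars are the mean and SD over 6 tumours. The differentiated keratinocyte list lies below 0 in every tumour in both panels, from -2.48 to -0.70 on the left and from -2.63 to -0.47 on the right.

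In keratinocyte-rich spots beside stroma-rich ones (the edge), genes of keratinocyte differentiation were lower than in the interior, while pigment cell and cell division genes were higher. TGM3, a transglutaminase of the upper epidermis, averaged 20.5 ± 19.7 CPM at the edge and 61.2 ± 47.8 CPM in the interior (SD, n = 6 tumours; log2 fold change -1.62, SE 0.20, edgeR adjusted p = 4.77e-04). PMEL, a structural protein of melanosomes, averaged 118.5 ± 162 against 49.8 ± 51.2 CPM (log2 fold change 1.23, SE 0.14, edgeR adjusted p = 1.38e-05). TOP2A, a topoisomerase of dividing cells, averaged 42.4 ± 28.7 against 27.5 ± 22.7 CPM (log2 fold change 0.64, SE 0.15, edgeR adjusted p = 0.0126). All 3 kept their direction in 6 of 6 tumours, which the rule for naming genes required. In tumour C PMEL was only 0.03 higher on the log2 scale. TGM3 lies on chromosome 20 (2296001 to 2341079, GRCh38), PMEL on chromosome 12 (55954105 to 55966709) and TOP2A on chromosome 17 (40388525 to 40417896).

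The contrast set 1701 edge spots against 2552 interior spots. The edge share of keratinocyte-rich spots was 38.0% in tumour A, 77.1% in B, 74.2% in C, 64% in D, 45.4% in E and 9.90% in F. In the median section stromal genes took 17.1 of 10000 UMIs in edge spots and 16.7 in interior spots, and keratinocyte genes 932.8 and 1127. The mean log2 ratio had a median over sections of 5.53 at the edge and, taken separately, 6.03 in the interior. Within a section the edge differed from the interior by -1.17 (tumour F, section 1) to 0.16 (tumour C, section 3). It was also above the interior in section 1 of tumours A and B. Depth differed as well, in either direction. The median UMI count per spot was 23105 at the edge and 11549 in the interior in section 2 of tumour A. In section 2 of tumour D it was 3167.5 and 5054. The medians over sections were 3262 at the edge and 3102 in the interior. Moran's I of the ratio, which is 0 for a random layout and near 1 for smooth areas, was 0.605 in tumour A, 0.199 in B, 0.191 in C, 0.393 in D, 0.545 in E and 0.780 in F. In tumours B and C, where 68% and 63.9% of spots lay within 0.5 log2 units of a class boundary, the classes thus hardly formed areas. Of 11268 genes tested with edgeR, 255 were higher and 654 lower at the edge, and 548 of these 909 had the same direction in all 6 tumours. Further genes that rose were the securin gene PTTG1 (0.63, SE 0.12), the chromatin protein HMGB2 (0.58, SE 0.11), the collagen-binding integrin ITGA2 (0.58, SE 0.11), the TGF-beta signal transducer SMAD4 (0.56, SE 0.12), the kinetochore gene SKA2 (0.55), the mannosidase MAN1A1 (0.59), the homeobox gene IRX4 (0.54), OAT (0.51), the metallothionein MT2A (0.51) and SOD1 (0.50). Further genes that fell were the glucose transporter SLC5A1 (-1.57, SE 0.20), LY6G6C (-1.51), ELOVL4 (-1.27) and DEGS2 (-1.15), which act in ceramide synthesis, GDPD3 (-1.25), the protease PRSS27, EPB41L3 (-1.19), BNIP3 (-1.18), SMIM5 (-1.18), the sterol reductase TM7SF2 (-1.15) and the tight junction gene CLDN4 (-1.11).

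Of the 24 differentiation genes 6 fell at the edge over all genes tested, CALML5 (-0.87), TGM3, DSG1 (-0.72), DMKN (-0.71), KRT10 (-0.76) and KRT1 (-0.82), and 19 fell when adjusted over the list alone. The camera adjusted p was 4.13e-25, with adjusted p = 0.271 with an estimated correlation, and the list mean was lower at the edge in 6 of 6 tumours. Cell cycle genes rose in 8 of 22 cases (15 adjusted over the list alone), including MCM3 (0.66), PCNA (0.41) and STMN1 (0.57), with a camera adjusted p of 8.61e-09 and adjusted p = 0.385 with an estimated correlation. Melanocyte genes rose in 4 of 6 cases (6 adjusted over the list alone), PMEL, MLANA (1.32), DCT (1.30) and TYR (1.57). Their camera adjusted p was 3.40e-09, with adjusted p = 0.134 with an estimated correlation, and this was the 1 list that fry also called (adjusted p = 0.00701). The melanocyte, cell cycle and basal lists were higher at the edge in 6 of 6 tumours.

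Basal keratinocyte genes had 1 of 15 members called, DST (0.38), which anchors keratin to the basement membrane, also 1 when adjusted over the list alone. camera gave 0.00106, and adjusted p = 0.385 with an estimated correlation. Invasion and matrix remodelling genes rose in 3 of 26 cases (4 adjusted over the list alone): the collagenase MMP13 (1.64, higher in 5 of 6 tumours), the urokinase PLAU (0.35) and the laminin receptor ITGA3 (0.36); camera gave 0.00153, and adjusted p = 0.529 with an estimated correlation. Hypoxia and glycolysis genes fell in 4 of 15 cases (5 adjusted over the list alone), BNIP3, HK2 (-0.70), VEGFA (-0.62) and ANGPTL4 (-0.39), with camera adjusted p = 0.00106 and adjusted p = 0.385 with an estimated correlation. Stress and immediate early genes fell in 5 of 14 cases (7 adjusted over the list alone), including IER2 (-0.37) and HSPB1 (-0.37), with camera adjusted p = 7.95e-04 and adjusted p = 0.412 with an estimated correlation. The mean of this list was lower in 3 of 6 tumours only, -0.45 in E, -0.65 in F and -0.04 in A, and from 0.01 to 0.09 in B, C and D. Interferon response genes fell in 3 of 15 cases (4 adjusted over the list alone), OAS1 (-0.54), IFIT1 (-0.64) and IFI27 (-0.36), with camera adjusted p = 7.95e-04 and adjusted p = 0.413 with an estimated correlation. Dendritic and Langerhans genes fell in 4 of 8 cases, also when adjusted over the list alone, CD207 (-0.91), CD1A (-0.59), FCER1A (-0.54) and CCL22 (-0.55), with camera adjusted p = 0.0165 and adjusted p = 0.385 with an estimated correlation. None of 10 mitochondrial transcripts passed, nor when adjusted over the list alone, while camera gave 0.0160 and adjusted p = 0.529 with an estimated correlation. The list mean was lower at the edge in 5 of 6 tumours for hypoxia, interferon response, dendritic and mitochondrial genes, and higher in 5 of 6 for invasion genes.

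The remaining lists were not called at the edge. Single members that passed were VWF of 14 endothelial genes (-0.44, camera adjusted p = 0.245), CD68 of 17 macrophage genes (-0.88, 0.226, lower in the 2 Visium tumours and 0 in the 4 others), CXCR2 of 8 neutrophil genes (-0.90, 0.179), AQP5, a water channel of sweat glands, of 13 gland genes (-1.35, 0.593), PSMB9 of 15 interferon gamma genes (0.40, 0.0518) and LTBP1 of 12 TGF-beta genes (0.44, 0.469). PSMB9 had -0.01 and was not called with each spot thinned to 500 UMIs. Of 7 B and plasma cell genes MZB1 rose (0.91) and SDC1 fell (-0.26), with camera adjusted p = 0.694. No member passed among 15 fibroblast (0.606), 7 pericyte (0.606), 14 T cell (0.103), 9 regulatory T (0.740) or 4 mast cell genes (0.925), where CD8A had 0.27 (SE 0.37), CTLA4 0.16 (SE 0.43) and CD274 -0.21 (SE 0.27). Adjusted over the list alone, 1 macrophage gene, 2 interferon gamma genes and 2 TGF-beta genes rose and 2 B and plasma cell genes fell, and the other counts of these lists were the same. FOXP3 and PDCD1 had too few counts to be tested at the edge, and 5 lists had fewer than 3 tested genes and no camera test (lymphatic endothelial, skeletal muscle, adipocyte, Schwann cell and red blood cell). Of these, NEB of 2 skeletal muscle genes (-1.50, lower in 4 of 6 tumours) and CIDEA, the 1 adipocyte gene (-0.68, lower in 5 of 6), passed; adjusted over the list alone, 2 skeletal muscle genes and 1 adipocyte gene fell and 1 Schwann cell gene rose. The mast cell list had a positive mean log2 fold change and the gland list a positive median, although camera gave both a downward direction.

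None of the 10 tumour-specific keratinocyte genes passed at the edge. Their log2 fold changes ran from -0.08 for PTHLH to 0.37 for IL24, with edgeR adjusted p-values from 0.257 for NT5E to 0.998 for MMP10, and 0 passed when adjusted over the list alone. SLITRK6, a membrane protein first described in neurons, was higher in 6 of 6 tumours without passing (0.32, SE 0.20, edgeR adjusted p = 0.361). The camera adjusted p was 0.164, with adjusted p = 0.581 with an estimated correlation. The mean of the list was higher at the edge in 5 of 6 tumours and lower in tumour E (-0.36). In simulated counts 57.9% of changes of 0.5 on the log2 scale were recovered at the edge, so smaller differences would often be missed.

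With thinned spots edgeR called 63 genes, 2 higher and 61 lower at the edge, of which 22 were among the 909, and with interior spots matched to edge spots on the keratinocyte to stroma ratio it called 413, 53 higher and 360 lower. limma voom with the stromal share as a covariate called 183, 9 higher and 174 lower, against 328 higher and 792 lower in voom without it. Most rises and most falls were thus not called once the share was in the model. With tumours A, E and F alone, chosen after the data were seen for their contiguous classes, edgeR called 754, 147 higher and 607 lower, of which 563 were among the 909. Without tumour A, D or E it called 594, 575 or 456, the DESeq2 test called 582, and 0 genes were called without the tumour block.

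**Figure D2:**
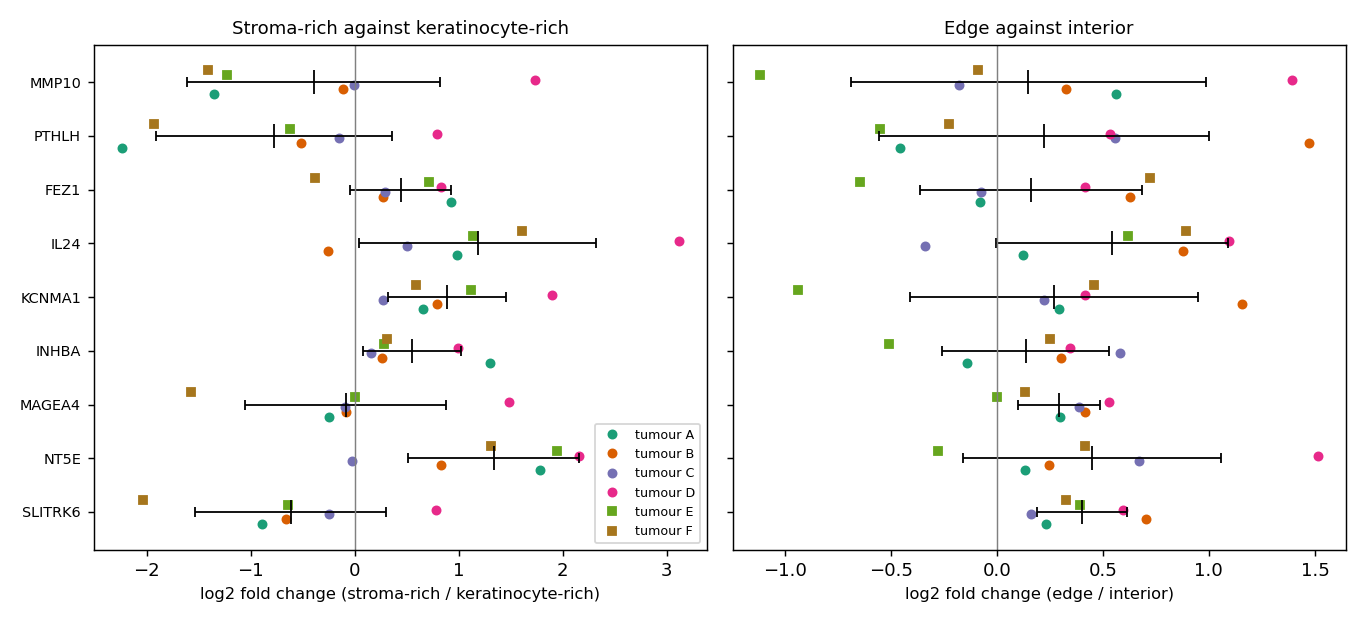
log2 fold change of 9 tumour-specific keratinocyte genes in each tumour (circles, ST; squares, Visium) for stroma-rich over keratinocyte-rich spots (left) and edge over interior spots (right); bars are the mean and SD over 6 tumours. Tumour D has the highest value for 7 of the 9 genes on the left, for example 3.12 for IL24, whereas on the right the points of most genes straddle 0. The kept spots of tumour D held only 642 UMIs of the whole list.

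Spots with more tumour-specific keratinocyte RNA tended to hold more basal and hypoxia RNA and less differentiation RNA. The list took 4.32 ± 0.11 of 10000 UMIs in tumour A (SD over sections, n = 3), 14.1 ± 0.72 in B (n = 3), 21.3 ± 1.03 in C (n = 3), 1.99 ± 0.94 in D (n = 3), 2.28 ± 0.09 in E (n = 2) and 8.06 ± 2.65 in F (n = 2). The partial Spearman correlation across spots averaged 0.29 ± 0.14 with the basal list and 0.16 ± 0.08 with the hypoxia list, both above 0 in 6 of 6 tumours, and -0.22 ± 0.15 with the differentiation list, below 0 in 6 of 6 (SD over 6 tumours). Each had an exact sign-flip permutation p of 0.031, the smallest that 6 tumours can give, and an adjusted p of 0.104 over the 10 relations computed. With 6 tumours a relation alone at the smallest p could not fall below 0.05 after adjustment over 10.

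Relations with stromal and immune lists were weaker. The mean correlation was 0.09 ± 0.15 with the B and plasma cell list and 0.08 ± 0.13 with the fibroblast list, each above 0 in 5 of 6 tumours (exact sign-flip permutation p = 0.156, adjusted p = 0.26). It was 0.09 ± 0.09 with the cell cycle list (5 of 6 above 0, exact sign-flip permutation p = 0.0938, adjusted p = 0.234) and 0.06 ± 0.10 with the T cell list (4 of 6, exact sign-flip permutation p = 0.219, adjusted p = 0.312). For regulatory T and checkpoint genes it was 0.05 ± 0.12 (4 of 6, exact sign-flip permutation p = 0.375, adjusted p = 0.469), for macrophage genes 0.05 ± 0.14 (2 of 6, exact sign-flip permutation p = 0.75, adjusted p = 0.75) and for endothelial genes 0.03 ± 0.12 (3 of 6, adjusted p = 0.694). Tumour E carried much of the stromal and immune means: without it they were 0.03 for B and plasma cell, 0.03 for fibroblast, 0.02 for T cell, 0.01 for regulatory T and checkpoint, -0.01 for macrophage and -0.01 for endothelial genes. Thus 0 of 10 relations passed adjustment and 3 had an unadjusted p under 0.05. Lists are shares of the same UMIs within a spot, so a rise of an abundant list lowers the others. The B and plasma cell list includes SDC1, which keratinocytes also express. Its average log2 CPM was 10.0 over stroma-rich and keratinocyte-rich sums, against 7.90 for JCHAIN. The correlation with this list is therefore not a measure of B and plasma cells alone.

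**Figure D3:**
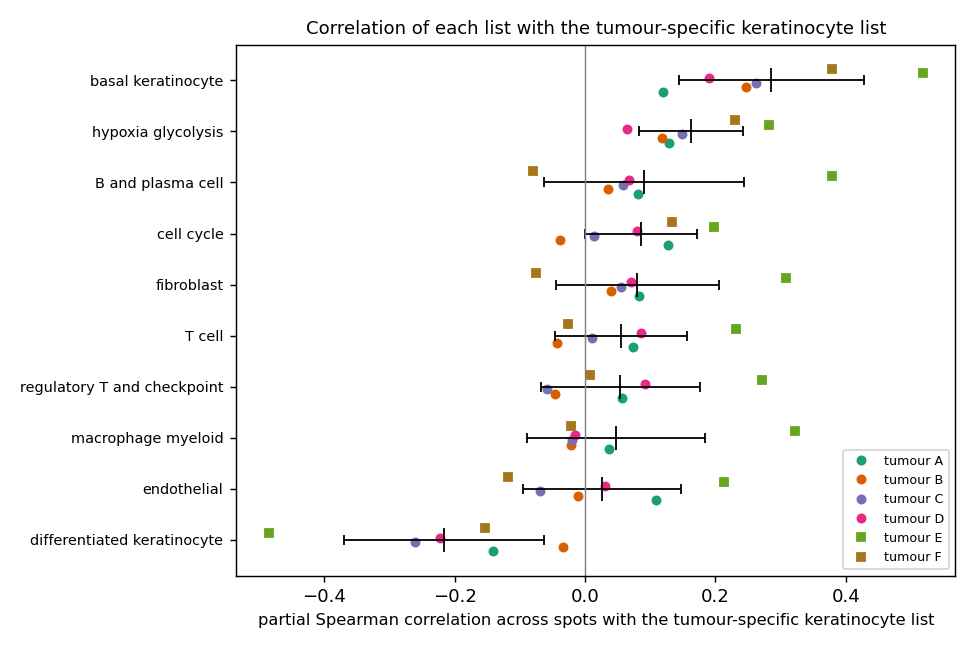
Partial Spearman correlation across spots between the tumour-specific keratinocyte list and 10 other lists in each tumour (circles, ST; squares, Visium), adjusted for the spot total; bars are the mean and SD over 6 tumours. The basal list lies between 0.12 and 0.52 and the differentiated list between -0.48 and -0.03 in all 6 tumours.

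The genes that set 1 tumour apart from the others of its platform included DCD, MAGEA4 and LOR. DCD did so on both platforms, for tumour A on ST and tumour F on Visium, and LTF for tumours D and F. Counts were summed over all spots over tissue, so these genes need not come from tumour cells. Among the ST tumours, tumour A had DCD, an antimicrobial peptide of sweat glands, at 1651 ± 203 CPM (SD, n = 3 sections) where no section of tumours B to D exceeded 4.10, together with PIP (187 ± 24.1 CPM), the cancer-testis gene CTAG2 (89.7 ± 7.58 CPM) and the neuronal pentraxin NPTX1 (88.4 ± 18.7 CPM). Tumour B had the cancer-testis gene MAGEA4 at 443 ± 40.0 CPM against at most 7.71 elsewhere, and also PRR9 (208 ± 35.4 CPM), JCHAIN (531 ± 142.5 CPM) and CORO6 (134.5 ± 27.3 CPM). Tumour C had the keratin KRT24 (180.5 ± 75.6 CPM), the neurofilament gene NEFL (918 ± 27.8 CPM) and MFAP5 (116 ± 18.4 CPM). Tumour D had the granule proteins LTF (250.2 ± 14.6 CPM) and TCN1 (614.5 ± 40.1 CPM) and the cornified envelope genes LOR (1589 ± 235 CPM) and HRNR (184 ± 17.5 CPM). edgeR adjusted p-values of these 15 genes ranged from 2.79e-33 for DCD to 6.63e-06 for HRNR.

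Over the ST sections edgeR found 9543 of 12061 genes to differ, and a median of 76.2% of a gene's variance lay between tumours. Gene lists followed: the differentiated list summed to 58300 ± 6635 CPM in tumour D and 19360 ± 2712 CPM in C, and the invasion list to 7536 ± 266 CPM in B and 1753 ± 346.5 CPM in D. The cell cycle list summed to 1597 ± 37.8 CPM in C and 497 ± 12.3 CPM in B, and the T cell list to 486 ± 66.3 CPM in B and 56.7 ± 7.21 CPM in C.

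Between the Visium tumours, tumour E had higher SPINK6, a kallikrein inhibitor (329 ± 39.4 CPM, n = 2 sections, against at most 10.9), and higher IGFL1 (1706 ± 267 CPM) and IGFL2 (416 ± 38.4 CPM). Tumour F had higher DCD (112 ± 18.0 CPM against at most 0.0903), LTF (157 ± 78.0 CPM) and the plasma cell genes MZB1 (215 ± 8.26 CPM) and TENT5C (77.4 ± 8.82 CPM). edgeR adjusted p-values of these genes ran from 2.15e-04 for MZB1 to 0.00267 for SPINK6. In all, 6672 of 14467 genes differed, with a median of 82.8% of variance between the tumours. The B and plasma cell list summed to 31400 ± 16140 CPM in F and 1884 ± 193 CPM in E, and the differentiated list to 96710 ± 508 CPM in E and 31370 ± 17330 CPM in F. Here the B and plasma cell list held 16 genes, among them immunoglobulin genes that the shared names lack. Its sums are thus not comparable with results on shared names or with the ST tumours, where it held 9 genes. With 2 sections a side the count rested on single sections. It fell without either section of tumour E and rose without either section of tumour F. In keratinocyte-rich spots alone edgeR called 3965 genes.

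The contrast between stroma-rich and keratinocyte-rich spots was not shown to differ between the platforms for any gene. edgeR called 0 of 12965 genes for the interaction, with a smallest adjusted p of 0.400 and 465 genes (3.59%) at an unadjusted p under 0.05. By camera with the preset correlation 14 of 28 lists differed, for example a larger stromal excess of endothelial genes (median interaction 1.04, adjusted p = 2.81e-10) and lymphatic endothelial genes (1.59, adjusted p = 1.51e-04) and a larger deficit of differentiated genes (-0.65, adjusted p = 4.86e-09) in the Visium tumours. With an estimated correlation the smallest of the adjusted p-values was 0.213, and 0 lists passed by that test or by fry. Platform and patient cannot be told apart here.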

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

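The tests of the differentiated keratinocyte list in thinned spots, against the fibroblast list and as a summed list were chosen after its fall at the edge had been seen. Its fit in matched spots and the regroupings were set out before. So was the mean change of the tumour-specific keratinocyte genes in matched and thinned spots, but not the sign-flip test of that list as a sum. No group of the design gives a biological explanation for these patterns, so no biological explanation was tested.

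The first pattern was the counts of calls themselves, set against regroupings of the same data. With the 2 classes swapped within tumours, 1 of 32 arrangements (the real one) reached the 4211 genes between stroma-rich and keratinocyte-rich spots, and the highest other gave 11; for edge and interior spots it was 1 of 32, with 909 genes against 500. Both pairs of classes rest on a ratio from the same counts. Edge and interior also differ in it in most sections, by -1.17 to 0.16 log2 units within a section. Genes that follow the ratio can therefore differ alike between tumours. The swaps favour the real arrangement between the regions and may favour it at the edge, and nothing is concluded from them for either gene count. For gene lists by camera chance cannot be excluded: 8 of 32 arrangements reached 17 lists between the regions (highest other 21), and 15 of 32 reached 10 lists at the edge (highest other 17). Among the ST tumours 1 of 100 regroupings of sections reached 9543 genes (highest other 5452).

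The second pattern was the fall of differentiated keratinocyte genes at the edge. In spots thinned to equal depth the summed list was still lower at the edge, by -0.453 log2 units on average (SD 0.32). It was lower in 6 of 6 tumours (exact sign-flip p = 0.031), against a mean of -0.77 (SD 0.45) as tested. Unequal depth of the summed spots is therefore not the whole cause. Thinned spots kept the edge and interior labels set on the full counts, so an effect of depth on those labels was not excluded. The fall exceeded the rise of the fibroblast list by 0.532 (SD 0.49, 6 of 6 tumours, exact sign-flip p = 0.031), but only by 0.04 in tumour B and 0.11 in D. Dilution by RNA that rises with the fibroblast list is therefore not the whole cause. RNA of other stromal or immune cells need not raise that list, so dilution by it was not excluded. With interior spots matched on the keratinocyte to stroma ratio the summed list fell by -0.45 (SD 0.32), and 5 of 6 tumours were lower (exact sign-flip p = 0.0625). Tumour F went from -1.61 to 0.06, so its fall ended. Of the mean fitted change 75.2% was kept.

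The third pattern was the tumour-specific keratinocyte list at the edge, whose mean fitted log2 fold change was 0.18. Matching kept 12.5% of it and thinning 267%, the latter over 6 of its 10 genes. Neither value can tell, because the summed list itself could not be told from 0 (mean 0.25, SD 0.47, 5 of 6 tumours higher, exact sign-flip p = 0.25).

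In 7 of 137 sets of 6 tumours 1 tumour lay far from the other 5, where chance alone marks about 5% of sets. For stroma-rich over keratinocyte-rich spots, tumour D had a mean log2 fold change of the tumour-specific keratinocyte list of 1.53 (others -0.45 to 0.24). Its kept spots held only 642 UMIs of this list, the fewest of the 6 tumours, so this value rests on low counts. At the edge, the interferon response list had 0.56 in tumour A (others -0.73 to -0.36) and TOP2A 3.60 in tumour B (others 0.17 to 1.19). The interior sum of tumour B held 331773 UMIs, the fewest of the edge and interior sums, so the TOP2A value can rest on few counts. In tumour F, SLC5A1 had -3.80 (others -1.59 to -0.88) and DEGS2 -2.68 (others -1.43 to -0.69). The correlation of the tumour-specific keratinocyte list in tumour E was 0.322 with the macrophage list (others -0.0212 to 0.0372) and 0.379 with the B and plasma cell list (others -0.0805 to 0.0806). The latter list includes SDC1, which keratinocytes also express.

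Array positions outside the tissue, which no comparison used, held 15.2% of the UMIs of tumour A, 43.0% of tumour B, 17.1% of tumour C and 22.2% of tumour D.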

How the results depend on the processing

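Of the values of the named genes and leading list members under the alternatives, 9188 kept their side of the threshold (and their direction where called), 778 lost the call, 172 gained it and 3 turned; for lists the counts were 549, 63, 27 and 2. Of 120 correlations 0 were called by the sign-flip test, but without 1 tumour or without tumours C and F the smallest possible p is above 0.05, so those settings say nothing of stability. Without tumour E 2 correlations changed sign (endothelial -0.0116, macrophage -0.00809). All 330 values of named genes between tumours were kept. Against 4211 genes between regions there were 986 with thinned spots (6557 genes tested; 927 of them among the 4211, and 66 of the 4211 with the opposite sign), 971 with 4 ST tumours, 2042 with 2 Visium tumours, 2587 without tumours C and F (added later), and 272 without the tumour block; leaving out a tumour gave 2382 to 4483 and a section 3880 to 4339. The 17 lists between regions became 0 with an estimated correlation. Against 909 edge genes there were 582 by the DESeq2 test, 63 with thinned spots (3169 tested; 22 of them among the 909, and 46 of the 909 with the opposite sign), 351 with 4 ST tumours, 375 with 2 Visium tumours, 0 without the tumour block, 413 with matched interior spots, 183 in voom with the stromal share as covariate (9 higher, 174 lower), 1120 in voom without it (328 higher, 792 lower, added later), 1663 with sums per section in voom and 1418 in edgeR (added later); leaving out a tumour gave 456 to 1011 and a section 716 to 983. The 10 edge lists became 0 with an estimated correlation and 1 by fry. With matched interior spots 9 were called, 2 higher and 7 lower, against 4 higher and 6 lower as tested. The sign-flip test of lists (added later) called 0 in both contrasts, which as many lists at the smallest p of 6 tumours would also have given. The 6672 genes between the Visium tumours became 3965 in keratinocyte-rich spots, and 895 to 9462 without 1 section, where the lone section is assumed to vary like the others. The 0 genes of the platform interaction became 0 to 1 without 1 tumour. Leaving out tumour B raised the calls between regions to 4483 and leaving out tumour A lowered them to 2382, so the number of tumours alone does not set the count. The other causes were not separated.

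Among the named genes and lists, those that turned were INHBA between regions (-0.0293) and PSMB9 at the edge (-0.0112) in thinned spots, IER3 at the edge in 4 ST tumours (0.0131), the mast cell list at the edge without tumour A (0.55; -0.19 to 0.55 without 1 tumour), and the camera direction of the mitochondrial list at the edge in thinned spots (-0.00902). The cause was not tested. Regions deposited by the authors were not run as classes, because the tables used hold none. Thinned spots left 3169 of 11268 genes to test at the edge.

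Section numbers were also tried as a replicate block on sums per section: 5688 genes between regions, 1450 at the edge, 9703 among ST tumours and 6162 between Visium tumours. The numbers do not pair the sections: the mean correlation of the 18 same-numbered ST pairs was 6.33e-04, 0 of them over 0.1, and 0.0095 for the Visium pairs.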

Other observations

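The tests of the cell cycle list in matched and thinned spots were chosen after its rise at the edge had been seen. Differentiated keratinocyte RNA was regionally clustered, with neighbouring spots alike, and had the highest mean of the 13 lists computed: Moran's I, which is 0 for a random layout and near 1 for smooth areas, averaged 0.58 (SD 0.17, n = 6 tumours). The interferon response list followed with 0.39 (SD 0.28), ranging from 0.10 to 0.88 between tumours (in tumour E 0.88 against 0.78 for the differentiated list), then basal keratinocyte genes with 0.34 (SD 0.19), macrophage genes with 0.29 (SD 0.23) and fibroblast genes with 0.28 (SD 0.20). The tumour-specific keratinocyte list had 0.24 (SD 0.16), hypoxia genes 0.23 (SD 0.12), cell cycle genes 0.16 (SD 0.15) and regulatory T and checkpoint genes 0.14 (SD 0.12). Lists with few UMIs per spot have lower values by sampling alone, so the order is not an order of biology only.

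Interferon response genes such as IFI27 and IFIT1 summed to 4771 ± 415 CPM in tumour B and 1918 ± 117 CPM in D (n = 3 sections each), and to 5845 ± 111 CPM in E and 4445 ± 19.0 CPM in F (n = 2 each).

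In keratinocyte-rich spots alone the tumour-specific keratinocyte list correlated with B and plasma cell genes at 0.20, with fibroblast genes at 0.13 and with T cell genes at 0.08, each above 0 in 6 of 6 tumours (exact sign-flip permutation p = 0.031, adjusted p = 0.0521). The other stromal and immune relations there were 0.08 with macrophage (5 of 6 tumours, exact sign-flip permutation p = 0.0938), 0.08 with endothelial (4 of 6) and 0.04 with regulatory T and checkpoint genes (4 of 6, exact sign-flip permutation p = 0.312). SDC1, which keratinocytes also express, had the highest average log2 CPM of the B and plasma cell genes tested at the edge (10.2). XBP1 had 6.61 and JCHAIN 5.79, so the B and plasma cell relation cannot be read as one with plasma cells. Cell cycle genes were higher at the edge in 6 of 6 tumours as a summed list (mean 0.48, SD 0.27), in matched spots (0.32, SD 0.21) and in thinned spots (0.55, SD 0.59), each with exact sign-flip p = 0.031. The thinned mean was highest in tumours B (1.23) and D (1.32), with 0.05 to 0.52 in the others. Only 7 of the 22 genes could be fitted in thinned spots, and their mean fitted change was 0.21 against 0.45 for the same genes in full spots.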
